A study of Arabidopsis thaliana with 8 samples.

How the data were processed

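Total RNA of Arabidopsis thaliana, wild type of the ecotype Columbia 0, was measured on gene expression arrays. Per the labels, 4 arrays held RNA of plants grown at normal CO2 and 4 held RNA of plants moved for 1 d to air with 1% CO2 by volume. The labels give the normal CO2 arrays as 0 d and name no group kept at normal CO2 for the same day. The effect of CO2 therefore cannot be told apart from that of the further day or of the move. The tissue, the plants' age, the labelling of the RNA and the type of array are not given in the sources used here. Nothing in the labels says that the 4 arrays of a group came from separate plants, so the p-values measure the spread between these arrays, which may be technical.

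The deposited values are relative spot intensities on a linear scale for 3439 probes. In every array the deposited intensity runs from 0 to 100, so all arrays share an upper limit. The background treatment and any normalization are not given in the sources used here, so the absolute scale stays unknown. The array medians were 0.256, 0.255, 0.221 and 0.227 for normal replicates 1 to 4 and 0.215, 0.212, 0.28 and 0.272 for high CO2 replicates 1 to 4. The highest median exceeded the lowest by 32.0%. The upper limit was reached by 5 probes on at least 1 array, 4 of the 5 on all normal arrays and 1 of the 5 on all high CO2 arrays. None of the 5 carries a single gene name, and their levels are only bounds. Between 133 and 219 probes per array were listed at 0.

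Values at 0 were treated as missing, the rest were put on the log2 scale, and a probe needed 3 values in each group, which left 3154 probes. A rule set before the data were examined called for quantile normalization between arrays when the medians differed by more than 10%, and it applied here. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 3154 probes and a threshold of 0.05. A positive log2 fold change means a higher level at high CO2. Means and SDs are of the deposited relative intensities, and log2 fold changes and their standard errors (SE) come from the normalized fit. The number of arrays limits the precision. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

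The platform annotation, updated through gene identifiers to the names of assembly TAIR10.1, gave 1 gene to 692 probes, several genes to 870 and no name to 1877. Of the 692, 690 matched the gene table. Only probes with 1 gene are named. AT2G25870, the one gene with more than 1 such probe in the test, is described with both. No coordinates are given, because no genome build is named for the probes.

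The genes named were set by a rule before the data were examined. It took the 10 probes with 1 gene and the largest rise, and the 10 with the largest fall, among those past the threshold whose 4 arrays of one group all lay above the 4 of the other. As applied, this needed a value above 0 on all 8 arrays. Called probes at 0 on an array, such as those of FBL17 (log2 fold change 3.16) and GH9B16 (-1.99), could not qualify. It added the 2 members with the lowest p of every gene list with at least 3 genes tested, and 12 genes of photosynthesis and carbon metabolism fixed by name, of which 0 were on a tested probe with 1 gene name. Of 28 lists with 405 genes fixed at the same time, 2 had 3 or more genes tested. A further 17 lists were drawn up from the probes' gene names after the data had been opened and before any fold change was computed; 16 had at least 3 genes tested, and they overlap the fixed lists. Lists were tested with limma's camera (preset correlation 0.01, missing values filled with the group mean, 1 probe per gene), adjusted within each set of lists, and also with an estimated correlation and with fry. The genes named from the added lists are the 2 with the lowest p of each, or were chosen after their values were seen.

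The script was tested on simulated data for the 3154 probes with 200 changed probes. With independent noise at the measured spread, 54% of the probes changed 2-fold and 92% of those changed 4-fold were recovered, and 3.10% of the calls were unchanged probes. When the noise shared the correlation of 0.55 seen within pairs of arrays, 31.9% of the calls were unchanged probes, against 7.32% with the pair as a random block. Camera was tried on simulated data with independent noise, where only the 16 pentatricopeptide repeat genes were shifted, by 1 log2 unit. It ranked that list 1 with no call among the others. This does not show its power for the fixed lists, with 3 and 5 genes tested. Nor does it cover data with paired noise or with 32.6% of the probes called, as here.

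The alternatives set in advance were median centring, values as deposited, a floor at the percentile 5 of each array, a pseudocount of 0.0549 (the percentile 10 of all positive values), leaving out the dimmest 25% of probes, a trended robust variance, a block for the replicate number, and leaving out each array in turn. Quantile normalization was listed as an alternative only for the case that the values were used as deposited, so it adds nothing here. Alternatives chosen after seeing the data were the pair of arrays as a random block or averaged, the set of arrays as a fixed block, each set alone, and removal of a running median over 49 neighbouring probe numbers.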

Results

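The data compared wild-type Arabidopsis plants grown at normal CO2 with plants kept for 1 d at 1% CO2, with 4 arrays in each group and 3439 probes per array. The question was which transcripts differ after that day at high CO2. The controls are labelled 0 d, so a difference may also come from the further day or the move. The 8 arrays had median relative intensities of 0.212 to 0.28 on a scale that ends at 100. Of the 3154 probes tested, 622 stand for a single named gene, so most of the changes counted here belong to probes that are not named.

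After 1 d at high CO2, 1029 of the 3154 probes had changed in the limma comparison, 452 of them higher and 577 lower. Of these, 193 carried a single gene name, 93 higher and 100 lower. A change of at least 2-fold was seen for 285 of the higher and 267 of the lower probes. Unadjusted p-values under 0.05 were found for 1413 probes, against 157.7 expected by chance. The split of the calls depended on the processing: 43.9% were higher after quantile normalization and 56.3% with the values as deposited, while the median log2 fold change of all probes was -0.16 and -0.07. It was 53.2% with pairs of arrays as a random block and 55% with the trend along the probe numbers removed (477 higher and 390 lower). Without normal CO2 replicate 1, 377 probes were lower.

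The arrays of a group were not evenly alike. Replicates 1 and 2, and replicates 3 and 4, of the same group correlated at 0.893 to 0.97 across probes, whereas arrays of the same group from different sets correlated at 0.855 to 0.902. The labels do not say what the sets are. With these pairs as a random block (estimated correlation 0.55), 442 probes passed, 235 higher and 207 lower. With each pair averaged, which leaves 2 values per group, limma called 0 probes, although 775 had an unadjusted p under 0.05. Within the sets, arrays 1 and 2 alone gave 909 calls and arrays 3 and 4 alone gave 850. Of these, 604 and 590 were among the 1029 with the same sign. Fold changes from the sets correlated at 0.49 across probes, which are not independent replicates. The count of 1029 therefore rests on treating all 8 arrays as independent.

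**Figure D1:**
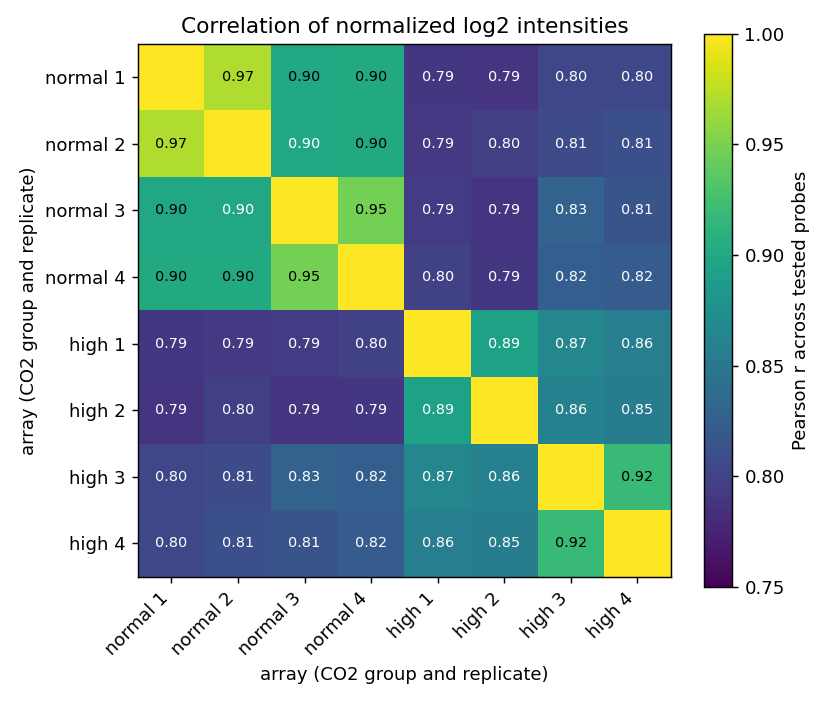
Pearson correlation of normalized log2 intensities across tested probes for each pair of the 8 arrays, named by CO2 group and replicate. Arrays of different groups correlated at 0.789 to 0.829, and the highest value, 0.97, was between normal replicates 1 and 2.

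**Figure D2:**
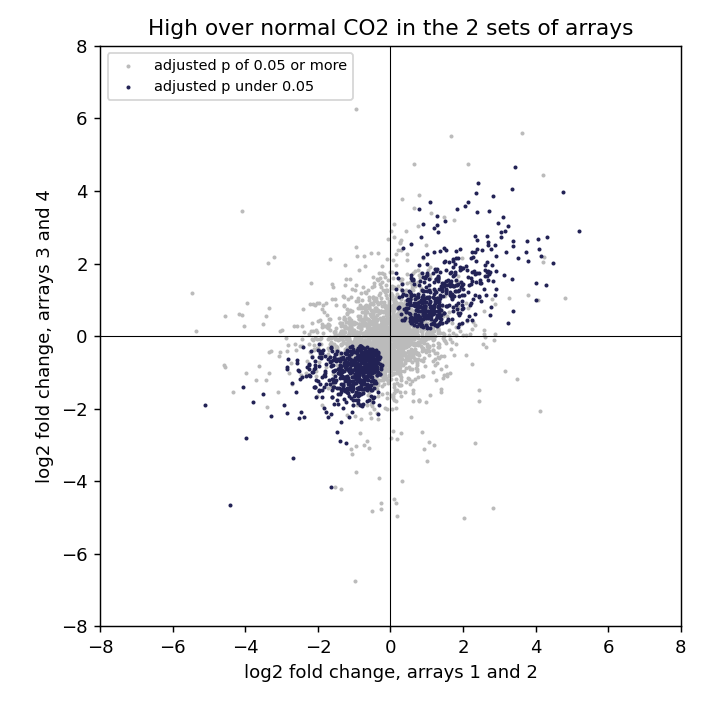
Log2 fold change of each probe, high over normal CO2, from arrays 1 and 2 (horizontal axis) and from arrays 3 and 4 (vertical axis). Dark points passed the adjusted threshold over all 8 arrays, which selects probes that moved the same way in both sets, and the correlation over all probes was 0.49.

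The largest rises among single-gene probes above 0 on all 8 arrays included transcripts with little signal in the control. AT3G56810 rose from a relative intensity of 0.767 ± 0.446 to 6.59 ± 0.969 (SD, n = 4 each), a log2 fold change of 3.18 ± 0.46 (SE, adjusted p = 0.00232 by limma). Its log2 fold change was 4.16 in arrays 1 and 2 and 2.21 in arrays 3 and 4. AT3G06870, which encodes a proline-rich protein, had the lowest adjusted p of these genes and rose from 0.489 ± 0.0297 to 3.42 ± 0.35 (SD, n = 4), or 2.69 ± 0.14 on the log2 scale (SE, adjusted p = 5.7e-05 by limma). AT5G46560 rose by 2.64 and AT1G51080 by 2.42 on the same scale. AT2G30100 rose by 3.03 and AT1G72020 by 2.36. AT5G19050 rose by 3.14, AT3G25680 by 2.91, AT5G41960 by 2.26 and AT2G23160 by 2.21, all from control intensities of 0.0298 to 0.0725. Without normal CO2 replicate 2 the value of AT5G41960 was 1.62. A pseudocount lowered these last 4 values to 2.03, 1.83, 1.57 and 1.3, in the order given.

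Among the largest falls were PSAN, the N subunit of photosystem I, and RPS6, a protein of the plastid ribosome. PSAN fell from 4.40 ± 0.519 to 1.81 ± 0.278 (SD, n = 4), a log2 fold change of -1.46 ± 0.19 (SE, adjusted p = 0.0014 by limma). RPS6 fell from 0.312 ± 0.0428 to 0.115 ± 0.0327 (SD, n = 4), or -1.57 ± 0.27 (SE, adjusted p = 0.00444 by limma), with -1.07 in arrays 1 and 2 and -2.08 in arrays 3 and 4. Among these genes AT2G41120 fell most, at -3.03 ± 0.39 (SE), which the pseudocount lowered to -2.01. AT2G32040, a member of the folate-biopterin transporter family, fell by 1.96, and AT1G79220, an mTERF protein, fell by 1.4. AT1G13970 fell by 1.85, AT1G21500 by 1.68, AT4G32340 by 1.5, AT2G48090 by 1.46 and AT1G04420, an aldo-keto reductase, by 1.4. The pseudocount gave -1.04 for AT1G21500.

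Of these 20 genes, 16 passed with the pair of arrays as a random block. The exceptions were AT5G41960 (adjusted p = 0.139), AT1G13970 (0.0727), AT4G32340 (0.106) and AT1G04420 (0.218). AT4G32340 also missed the threshold with the values as deposited (adjusted p = 0.076) and without any of the 4 normal arrays or without high CO2 replicate 1 (0.0587 to 0.0752), and AT1G04420 without normal replicates 1, 3 or 4 or without high CO2 replicate 2 (0.0526 to 0.0663). Removing the position trend also ended the calls of AT4G32340 (log2 fold change -1.09 ± 0.42 SE, from -1.5 ± 0.44; adjusted p = 0.0881) and AT1G04420 (-1.08 ± 0.38, from -1.4 ± 0.39; 0.0654). AT1G13970 was at -2.86 in arrays 1 and 2 and -0.84 in arrays 3 and 4, and AT4G32340 at -2.11 and -0.90.

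**Figure D3:**
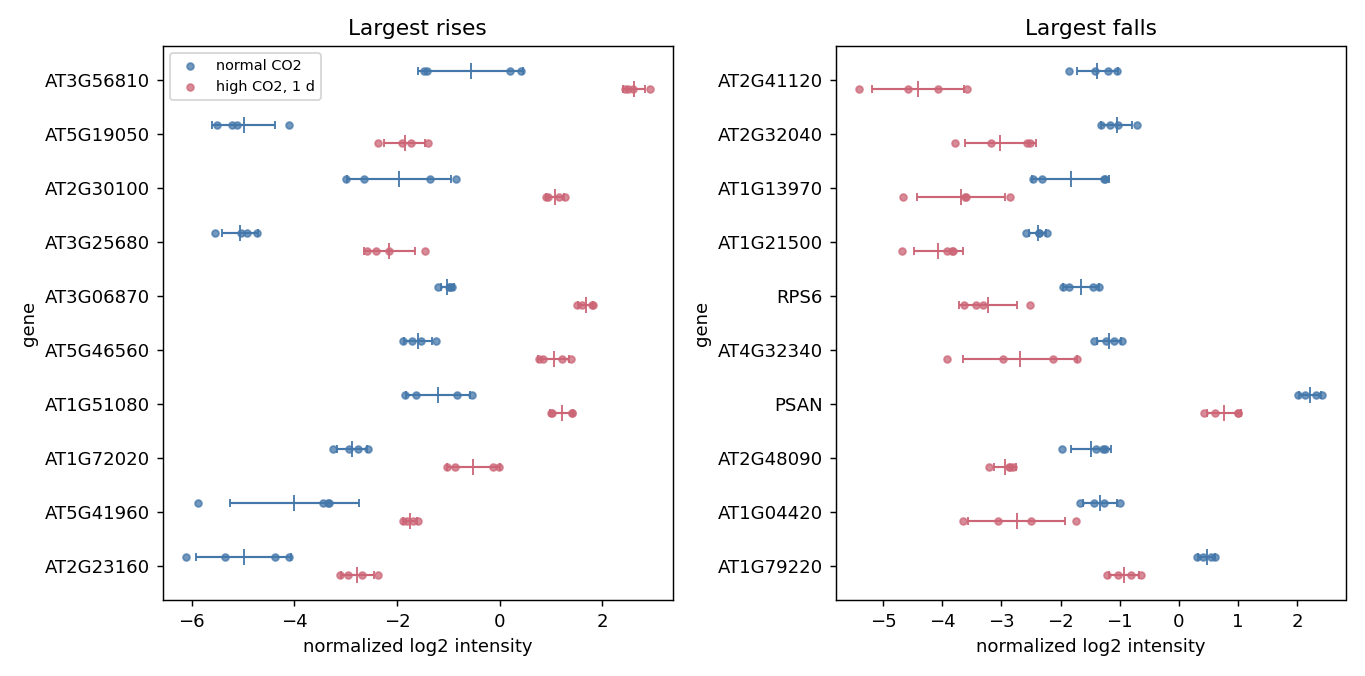
Normalized log2 intensity on each array (points) for the 10 largest rises and the 10 largest falls among single-gene probes, with the mean and SD of the 4 arrays of each CO2 group. In every gene shown the 4 arrays of one group lie above the 4 of the other, as the rule for choosing them requires, and AT3G56810 rose by 3.18 on the log2 scale.

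Of the 405 genes in the lists fixed in advance, 21 were tested, and 7 of them fell, 2 rose and 12 did not pass. Among all tested probes 32.6% were called. Coverage was low, with 2 of 24 Calvin cycle genes and 1 of 25 photorespiration genes tested, so single genes do not stand for their pathways. The 7 that fell were PSAN, the plastid ribosomal proteins RPS6, RPS10 and RPL34, the Calvin cycle enzyme SBPASE, the chlorophyll synthesis enzyme CHLM, and FTRB, the catalytic subunit of ferredoxin-thioredoxin reductase. SBPASE fell from 0.679 ± 0.12 to 0.386 ± 0.0602 (SD, n = 4), a log2 fold change of -0.87 ± 0.18 (SE), CHLM by 1.07 and FTRB by 0.63 on that scale. The 2 that rose were PSBW, a small subunit of photosystem II, and FATB, a thioesterase of plastid fatty acid synthesis, at 1.18 ± 0.18 (SE). Of these 9 calls, 4 passed with the pair of arrays as a random block, namely PSAN, RPS6, FTRB and FATB. Removing the position trend ended the call of FTRB (log2 fold change -0.34 ± 0.14 SE, from -0.63 ± 0.13; adjusted p = 0.111). The other Calvin cycle gene tested, PRK (phosphoribulokinase), had a log2 fold change of -0.47 with an adjusted p of 0.0548. Also not past the threshold were LHB1B2 of the light-harvesting antenna at -0.31, LrgB of the photorespiration list at -0.34, and ATSPS4F, a sucrose phosphate synthase, at -0.11 (0.08 with the values as deposited). CHLP of chlorophyll synthesis (0.07), KAR of fatty acid synthesis (0.13), and NTRC (-0.34) and PRXIIE (0.21) of the antioxidant list did not pass either.

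The plastid ribosomal proteins had a median log2 fold change of -0.62. Of the 5 tested, 3 fell, RPS6, RPL34 (-1.22 ± 0.31 SE) and RPS10 (-0.62), and RPL17 (-0.30) and RPL5 (-0.04) did not pass, with 3 also passing when adjusted over the list alone. Against all other probes the list did not pass camera (adjusted p = 0.147, and adjusted p = 0.235 with an estimated correlation), while fry, which asks whether the members move one way on balance, gave an adjusted p of 0.000589. Fry makes no comparison with other probes and took all arrays as independent. RPL34 missed the threshold without normal CO2 replicate 4 (adjusted p = 0.0511), and RPS10 without normal replicates 1, 3 or 4 or high CO2 replicates 1, 3 or 4 (0.0525 to 0.0676). RPL5 turned to 0.03 with the values as deposited.

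In the photosystem II core, PSBW rose from 24.1 ± 5.72 to 41.9 ± 2.69 (SD, n = 4), or 0.67 ± 0.16 on the log2 scale (SE, adjusted p = 0.0155 by limma). It missed the threshold without normal CO2 replicate 1 (adjusted p = 0.0582), without replicate 2 (0.0588) and with the pair as a random block (0.0566). PSB27, a lumenal protein of photosystem II assembly and repair, had a log2 fold change of -1.07 (adjusted p = 0.0601), with -1.91 in arrays 1 and 2 and -0.23 in arrays 3 and 4; it passed with median centring (0.0371), without the dim probes (0.0396), with the trended robust variance (0.0315), without high CO2 replicate 3 (0.0269) or 4 (0.0491), with the array set as a fixed block (0.0492) and in arrays 1 and 2 alone (0.0141). PSBY was at -0.38 (adjusted p = 0.0679) and passed under 4 alternatives, with the dim values floored (0.0274), with the pseudocount (0.0449), without the dim probes (0.0467) and with the trended robust variance (0.0326). Adjusted over the list alone, all 3 members passed, and they did not share a direction, with a list median of -0.38 (-0.01 without the position trend) and an adjusted p of 0.825 by camera (adjusted p = 0.831 with an estimated correlation). By camera 0 of the 2 fixed lists with 3 or more genes passed, 0 at an unadjusted p under 0.05, and fry called 1.

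**Figure D4:**
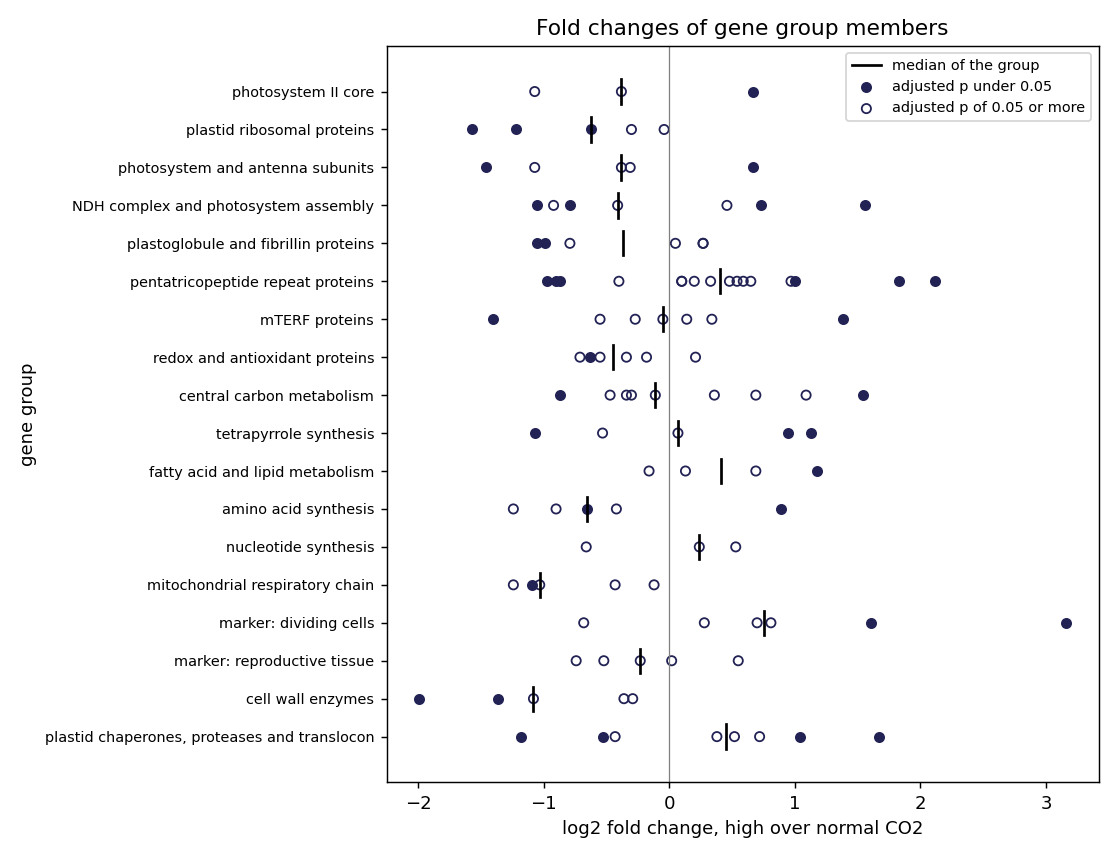
Log2 fold change, high over normal CO2, of each tested member of the gene groups with at least 3 genes tested. Filled points passed the adjusted threshold, bars mark group medians, and the first 2 groups were fixed before the data were examined; the plastid ribosomal proteins have a median of -0.62.

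AT2G25870, the one gene with a pair of single-gene probes in the test, gave opposite results on them. On the first its log2 fold change was -0.85 ± 0.16 (SE, adjusted p = 0.00652 by limma), and on the second 1.09 ± 0.24 (SE, adjusted p = 0.0114 by limma). The second missed the threshold with the pair as a random block (adjusted p = 0.0616 by limma), which leaves the fold change of a probe measured on all arrays as it was. Without the position trend its log2 fold change was 1.07 ± 0.34 (SE, adjusted p = 0.0512 by limma), where the call ended because the error grew. Why the probes differ was not tested. The other genes named have 1 such probe each, so their names were not checked in this way.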

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

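The tests of the pair of arrays as a random block, of averaged pairs, of the scaling and of the highest correlation over all distances were chosen after the result was seen. Among 144 groups of 4 arrays, 10 had an array far from the other 3, where chance gives about 7.2. The gap to the nearest array took up 0.953 of the group's range for AT5G41960 at normal CO2 (replicate 2, log2 intensity -5.89 against -3.44 to -3.32 in the others). The share was 0.877 for AT1G21500 at high CO2 and 0.849 for AT2G48090 at high CO2, both in replicate 1. It was 0.959 for PYG7 and 0.928 for the second probe of AT2G25870, both in normal replicate 3, and 0.884 for ATSPS4F in high CO2 replicate 2. For PSBW at high CO2 it was 0.914, in replicate 1, where the values lie close together (5.28 against 5.38 to 5.39). It was 0.84 for GLDH (normal replicate 2), 0.836 for CBL (normal replicate 3) and 0.831 for FBL17 (high CO2 replicate 4, at -4.63 against -2.98 to -2.65).

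The count of 1029 changed probes was weighed against a chance split, the pairing of arrays and the scaling. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many calls, the real one, and the highest of the others gave 5. That would exclude chance only for exchangeable arrays. Within each group the arrays of a pair were more alike than arrays of different sets, so the splits cannot decide. Only 3 splits keep every pair of arrays whole, too few for a share under 0.05. Pairing stays open for all the calls, since near-repeat arrays may have made the p-values too small. With the pair as a random block, which takes 1 correlation of 0.55 for all probes, 442 probes passed. Averaging the pairs, which takes no such correlation, left 0 calls by limma, with 775 at an unadjusted p under 0.05 against 157.7 by chance. In 20 simulated unchanged data sets with paired noise the highest count was 13, which lies below the bound set before the result was seen, the observed count divided by 3. That bound was wrong, since the simulated probes varied independently, whereas differences between array sets correlated at up to 0.363 between probes 6 numbers apart. Median centring, which takes out a constant factor per array, gave 970 calls. It is no test of such a factor, since quantile normalization had already taken it out of the values behind the 1029 calls. The values as deposited gave 886 calls, but they keep the submitters' scaling and cannot decide. Other effects of that scaling or of the background treatment stay open.

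Fold changes were alike at neighbouring probe numbers, with a correlation of 0.198 across probes 6 numbers apart. That distance was picked as the highest of 17 tried. A permutation of the probe order gave p = 5e-04 (one-sided) for the highest correlation over all 17, the smallest that 2000 orders can give, and p = 1e-04 at the picked distance alone, the smallest that 10000 orders can give. The difference between arrays 3 and 4 and arrays 1 and 2 of one group, which holds no treatment, had a correlation of 0.363 at that distance at normal CO2 and 0.119 at high CO2. That is consistent with a position or plate effect on the arrays, as a hypothesis. At normal CO2 that difference was most alike at distance 1 (0.454) and the mean signal at 6 (0.21). At 12 the correlation was 0.172 for the fold change, 0.188 for the mean signal, and 0.305 and 0.11 for the differences at normal and high CO2. Whether these distances reflect a plate layout was not tested. Fold changes that follow the mean signal are argued against, since they correlated with it at -0.002, and removing their smooth dependence on it left 0.197. Without the brightest 25% of probes the correlation was 0.227. That cannot decide on spill-over from bright spots, since dim probes near the same bright spot stay in and the array layout is unknown. A biological cause, such as related genes placed side by side, was not tested.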

How the results depend on the processing

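The random block, averaging, array sets, fixed set block and position trend were chosen after seeing the data. Across all alternatives the 23 genes of the naming rule kept their sign in 479 of 479 values. Most of these genes were chosen because their groups do not overlap, so leaving out, averaging or splitting arrays could hardly turn their sign. Of the 479 values, 52 called ones lost the threshold, 22 of them on averaging pairs, and 7 uncalled ones passed. No gene list passed camera under any alternative it was run with; it was not run with the random block. With pairs averaged 0 probes were called, 0 higher and 0 lower, with 775 at an unadjusted p under 0.05. The number of values alone does not explain this, since 2 arrays per group from a single set gave 909 and 850 calls. With the pair as a random block 442 were called, 235 higher and 207 lower, all among the 1029. Leaving out each array gave 730 to 914 calls, 353 to 406 higher, 377 to 516 lower (377 without normal replicate 1) and 1202 to 1326 at an unadjusted p under 0.05. The position trend's removal left 867 calls, 477 higher and 390 lower, 713 of them among the 1029, and moved the median of all probes from -0.16 to -0.04; floored values gave -0.06.

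The replicate numbers were not taken to pair the samples, since deviations of same-numbered arrays correlated at 0.039, 0.093, 0.133 and 0.053, not all over 0.1. As a hint of pairing, 7 of the 8 arrays correlated best with their own number; normal 1 was closest to high 2. The replicate block called 845 probes, 404 higher and 441 lower, 1373 at an unadjusted p under 0.05, and 0 gene lists. Among called genes named in the text, AT1G13970, CBL, FBL17, AT4G14330, RPS10, PYG7, AT3G04210, TIG, CTPA and CRR41 missed the threshold with it (adjusted p = 0.0516 to 0.138).

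Medians of lists that did not pass changed sign, and the cause was not tested: NDH complex and photosystem assembly (0.02 without dim probes, 0.04 in arrays 1 and 2, -0.58 to 0.08 leaving out each array), plastoglobule proteins (-0.78 to 0.05 leaving out each array), mTERF proteins (0.02 as deposited, -0.18 to 0.02 leaving out each array, 0.26 without the position trend), central carbon metabolism (0.01 median centred, 0.08 as deposited, 0.22 in arrays 3 and 4, 0.15 without the position trend), tetrapyrrole synthesis (-0.08 to 0.21 leaving out each array, -0.18 in arrays 1 and 2), fatty acid and lipid metabolism (-0.02 in arrays 3 and 4), reproductive markers (0.02 without dim probes, 0.05 without the position trend) and plastid chaperones (-0.43 without dim probes). So did fold changes of single genes that did not pass: AT2G44530 (0.07 in arrays 3 and 4), LHB1B2 (0.03 without the position trend), ATSPS4F (-0.31 to 0.09 leaving out each array, 0.01 median centred, 0.08 as deposited, 0.5 in arrays 3 and 4, 0.24 without the position trend), CHLP (-0.08 to 0.21 leaving out each array, -0.18 in arrays 1 and 2), RPL5 (-0.19 to 0.25 leaving out each array, 0.03 as deposited, 0.01 with the pseudocount, 0.31 in arrays 3 and 4, 0.19 without the position trend), PRXIIE (-0.2 in arrays 3 and 4) and KAR (-0.19 to 0.35 leaving out each array, -0.43 in arrays 3 and 4). Calls were rarer among dim probes, 18.9% in the dimmest 25% of probes and 46.5% in the brightest 25%.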

Other observations

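All gene lists in this part were drawn up after the data had been opened, before fold changes were computed. Among proteins that build the photosynthetic complexes, LPA19 and the rubredoxin RBD1, both needed for photosystem II assembly, fell by 1.05 and 0.79 on the log2 scale and also passed with the pair of arrays as a random block (adjusted p = 0.0131 and 0.0377); without the position trend LPA19 was at -0.65 (adjusted p = 0.0192) and RBD1 did not pass. CRR41 and PYG7 were higher by 0.73 and 1.56, but not past the threshold with the random block (adjusted p = 0.144 and 0.163); PYG7 was at 0.58 in arrays 1 and 2 and 2.54 in arrays 3 and 4. The other 3 of the 7 tested did not pass. BSD2, a Rubisco assembly chaperone, rose from 1.52 ± 0.18 to 3.46 ± 0.522 (SD, n = 4), and CTPA rose by 1.67, while the translocon subunit SECE1 fell by 1.18 and TIG by 0.53 (-0.35 with the pseudocount and -0.83 without the position trend); 4 of those 8 did not pass. The fibrillins FBN2 and AT2G46910 fell by 0.99 and 1.05, and 4 of 6 plastoglobule proteins did not pass. Of 16 pentatricopeptide repeat proteins 3 rose, led by AT5G39980 at 2.12 ± 0.17 (SE), 3 fell, among them AT3G26630 at -0.97, and 10 did not pass. AT5G39980 was fitted with 3 of the 4 normal arrays, the other being at 0, and was at 2.3 with the pseudocount. Of 7 mTERF proteins AT4G09620 rose by 1.38, AT1G79220 fell by 1.4 and 5 did not pass.

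The endoglucanase genes GH9B16 and GH9B11 fell by 1.99 and 1.36, with 3 of 5 cell wall enzymes not passing. GH9B16 was fitted with 3 of the 4 high CO2 arrays, the other being at 0, and was at -1.6 with the pseudocount. Among 6 genes of dividing cells FBL17 and AT4G14330 were higher, from signals at the percentiles 3 and 6 of all probes and with 3 of the 4 normal arrays measured. FBL17 went from 0.0108 ± 0.012 to 0.117 ± 0.0505 (SD, n = 4 each, the normal array at 0 counted as 0). Its log2 fold change, which leaves that array out, was 3.16 ± 0.65 (SE), with 4.28 in arrays 1 and 2 and 1.4 in arrays 3 and 4. For AT4G14330 the log2 fold change was 1.61 ± 0.49 (SE). The pseudocount lowered these values to 1.42 and 1.03, so their size is uncertain. In tetrapyrrole synthesis HEMA3 rose by 0.95, AT5G63290 rose by 1.13 and CHLM fell by 1.07. In amino acid synthesis CBL fell by 0.65 and DAPF rose by 0.89, in central carbon metabolism AT4G17260 rose by 1.54 beside the fall of SBPASE, and in the mitochondrial respiratory chain ATP11 fell by 1.09, with 3, 7 and 4 members not passing. In fatty acid and lipid metabolism FATB alone of 4 passed, among redox proteins FTRB alone of 6, and among photosystem and antenna subunits PSAN and PSBW of 5. Of the 2 TIR-NBS proteins tested AT3G04210 rose by 0.52. None of the 3 nucleotide synthesis genes and none of the 5 reproductive tissue markers passed. By camera 0 of the 16 lists with at least 3 genes passed, 2 had an unadjusted p under 0.05 (dividing cells, p = 0.0315, and cell wall enzymes, p = 0.0296, by limma's camera, each with an adjusted p of 0.252 and an adjusted p of 0.602 with an estimated correlation). Fry called 10 of the 16 in one direction and 13 in either direction. It does not compare a list with the other probes, and 32.6% of all tested probes were called. It also took all arrays as independent, so its calls do not single out these lists.

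Of the 31 called probes named outside the naming rule, which stand for 30 genes, 21 kept their call on leaving out each array in turn and 15 kept it with the pair of arrays as a random block. The 10 that lost it on leaving out at least 1 array were DAPF, CBL, ATP11, AT4G14330, RPS10, PYG7, AT3G04210, TIG, CTPA and CRR41, with a highest adjusted p of 0.0634 (DAPF) to 0.0937 (PYG7). These 10 also missed the threshold with the random block, as did SBPASE (adjusted p = 0.0701), AT4G17260 (0.079), FBL17 (0.0674), SECE1 (0.0521), CHLM (0.0536) and the second probe of AT2G25870 (0.0616). Removing the position trend ended 7 of the 31 calls. The log2 fold change (± SE) shrank for RBD1 (-0.79 ± 0.16 to -0.41 ± 0.18), FTRB (-0.63 ± 0.13 to -0.34 ± 0.14), SECE1 (-1.18 ± 0.21 to -0.71 ± 0.24), CBL (-0.65 ± 0.18 to -0.28 ± 0.15) and ATP11 (-1.09 ± 0.31 to -0.77 ± 0.32). It stayed about as large for CRR41 (0.73 ± 0.21 to 0.62 ± 0.23) and the second probe of AT2G25870 (1.09 ± 0.24 to 1.07 ± 0.34), where the error grew. The adjusted p of these 7 was then 0.0512 to 0.205. In arrays 1 and 2 against arrays 3 and 4, the log2 fold change was 2.75 and 0.59 for CTPA, 1.12 and 0.33 for CRR41, 0.89 and 2.19 for AT4G17260, and 0.63 and 1.56 for the second probe of AT2G25870.

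Of the probes left out of the comparison, 80 were measured on all normal arrays and listed at 0 on at least 2 high CO2 arrays, against 12 the other way round. They are part of the 196 to 219 probes at 0 per high CO2 array, against 133 to 174 per normal array, and the cause was not tested. The arrays with the highest medians, high CO2 replicates 3 and 4 (0.28 and 0.272), also had more probes at 0 than any normal array.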
